A study of Mus musculus with 32 samples.

How the data were processed

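Gene expression was measured by stranded paired-end RNA sequencing of total RNA from the hypothalamus of 32 male C57BL/6NTac mice. The libraries were hemizygous Gpr101 knockouts on control diet (KO_CD, 8 mice) or high-fat diet (KO_HFD, 9 mice) and wild-type littermates on control diet (WT_CD, 7 mice) or high-fat diet (WT_HFD, 8 mice), with each group taken from the labels. The submitters' processing notes name Trim Galore 0.6.2, cutadapt 2.10, FastQC, STAR 2.7.6a, DESeq2 1.28.1, R 4.0.2 and the mouse build GRCm38. The counting tool, its strand setting and the gene annotation are not given in the sources used here.

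The deposited values are on a log2 scale, 1 per gene and library. In every library they equal the log2 of a whole read count divided by a library size factor, and a count of 0 is listed as the log2 of 0.1. Undoing the log and dividing by the step of 1 read returned whole reads for 100.0% of the values above that floor, within a tolerance of 1e-06 reads and with a largest deviation of 1.18e-08. The steps matched median-of-ratios size factors recomputed from those reads to within 0.0072%. The series table and the single-library tables differed by at most 0.0005 on the log2 scale. Of 55401 gene identifiers, 55141 were paired with a symbol and coordinates in a GRCm38 annotation and 260 were not.

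Reads on genes ranged from 25.3 to 34.2 M (megareads) per library, with a median of 27.7 M, so that 1 read corresponded to 0.0361 CPM (counts scaled to 1 M reads on genes) at the median. The lowest correlation of log2 values between any pair of libraries was 0.9859, and no pair was treated as a repeat of 1 library. Counting intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules. Each library came from a separately labelled mouse.

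The design fixed before the data were examined named a quasi-likelihood test of counts. Because the deposited unit is log2 and not counts, limma 3.58.1 in R 4.3.3, with statmod 1.5.0, was used in its place, although the recovered reads would have allowed the planned test. Values were log2(normalized count + 1), and a gene was tested when its normalized count reached 10 in at least 7 libraries, which kept 19928 genes. The pseudocount of 1 makes the fold changes of genes with few reads smaller than the change in their reads. All 4 groups entered 1 fit without covariates, with an intensity trend and robust moderation of the variances, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were genotype on each diet, diet in each genotype, genotype averaged over diets, diet averaged over genotypes, and the interaction of genotype and diet. All tests were two-sided.

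There were 37 gene lists, fixed before the data were examined, which covered feeding peptides, hormone signalling, cell types, neighbouring brain regions, metabolism, stress and the neighbours of Gpr101. They were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were chosen at the same time, and a permutation of the mean of a list per library was added after the data were seen. In random splits of the mice, camera with the preset correlation called a median of 5 to 7 lists per comparison. A list called by that test alone may therefore be due to chance. Where single comparisons of a list mean are reported, the test was an exact permutation test over all splits of the mice, and for averaged comparisons a permutation test with 100000 random splits within each diet or genotype. The named genes followed a rule fixed before the data were examined. It takes Gpr101, up to 10 higher and 10 lower called genes of largest fold change per comparison with a symbol other than a predicted-gene name and a mean of at least 1 CPM, a panel of 20 hypothalamic genes whether called or not, up to 4 members (2 higher and 2 lower, by p) of each list that passed its test or held a called gene, called neighbours of Gpr101, and genes called in the interaction. Of the panel, values are given for genotype on each diet and for diet averaged over genotypes, and for the other comparisons in part. Genes named outside it are stated to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

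The test was checked on simulated data in which 50 genes were changed at each fold, and a further list of 20 genes, 19 of them tested for genotype on control diet, by 1.25-fold. The simulated genes varied independently of each other, without the structure that genes of a real library share. The shares and false calls below therefore hold for such data and may not carry over to the mice. Many changed genes also loosen the Benjamini-Hochberg cutoff. The shares therefore overstate what could be called where few genes change, such as between genotypes, where 1 gene was called. For genotype on control diet, 60% of genes changed 1.25-fold were called, 78% of those changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold, over 19763 genes, and 6 of 177 calls were unchanged genes. For diet averaged over genotypes the shares were 76%, 88%, 92% and 100% over 19756 genes, and 10 of 200 calls were unchanged genes. For diet in wild type they were 54%, 66%, 84% and 98% over 19776 genes, and 4 of 167 calls were unchanged genes.

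Alternatives changed 1 choice at a time, except that limma-voom with quality weights changed the test and the weights together. They covered the filter, the pseudocount, library sizes, limma-voom on the recovered reads with and without quality weights, robust moderation, the groups in the fit, age, the order of label numbers, replicate numbers, residual components, marker means of meninges and blood, and the libraries and ages included. Figures were drawn with matplotlib 3.10.9.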

Results

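The series measured how loss of Gpr101 and a high-fat diet altered gene expression in the mouse hypothalamus, the brain region that controls feeding, energy use and pituitary hormones. Gpr101 encodes an X-linked orphan receptor that signals through Gs and is abundant in hypothalamic neurons. Adult male knockouts and wild-type littermates received control diet (KO_CD, 8 mice, and WT_CD, 7 mice) or a diet with most of its energy from fat (KO_HFD, 9 mice, and WT_HFD, 8 mice). Reads on genes per library averaged 28.2 ± 2.52 M in KO_CD, 27.6 ± 0.879 M in KO_HFD, 28.1 ± 1.29 M in WT_CD and 28.7 ± 2.40 M in WT_HFD (SD). Mice were killed at 149 or 150 days, and age followed diet closely. There were 5 KO_CD, 1 KO_HFD, 6 WT_CD and 1 WT_HFD mice of 149 days, and the other mice were 150 days old.

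Gpr101 (ENSMUSG00000036357, GRCm38 chromosome X, 57496668 to 57503757, minus strand) was the first gene examined, since it is the targeted gene. It was abundant in wild type, at 101.25 ± 3.72 CPM on control diet (SD, n = 7) and 102.18 ± 3.95 CPM on high-fat diet (SD, n = 8), from 2605 to 3145 and from 2471 to 3472 reads per library. The 8 KO_CD libraries together held 0 reads of 225.6 M, which allows up to 0.0133 CPM (3 reads over the group), so the transcript was at least 7614-fold lower than in wild type. The 9 KO_HFD libraries held 1 read of 248.6 M, in KO_HFD replicate 4, and the wild-type level was 25403 times that of the knockout (counting interval 4559 to 1003367). In the limma fit the log2 fold change was -11.47 (SE 0.12, adjusted p = 4.05e-49) on control diet and -11.37 (SE 0.12, adjusted p = 3.57e-50) on high-fat diet, values that depend on the pseudocount. Each library carried the Gpr101 level of its label.

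**Figure D1:**
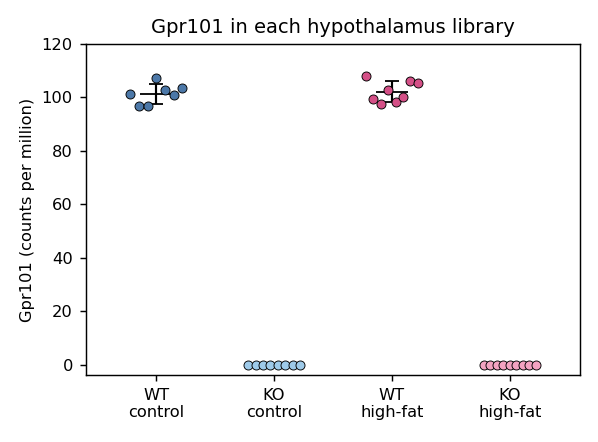
Gpr101 in CPM of reads on genes, on a linear axis, with 1 point per library and the group mean ± SD as bars. Wild-type libraries averaged 101.25 CPM on control diet and 102.18 CPM on high-fat diet, and knockout libraries held 0 or 1 read.

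On control diet, genotype was compared to ask which hypothalamic genes depend on Gpr101 without a dietary load. Gpr101 itself was lower, and no other gene passed the test (the smallest adjusted p among the others was 0.429). The feeding peptide genes missed the threshold. Npy, encoding the orexigenic neuropeptide Y, had a log2 fold change of -0.38 (SE 0.14, adjusted p = 1), and Agrp, encoding its partner agouti-related peptide, of -0.29 (SE 0.15). Pomc, the precursor of the satiety peptide alpha-MSH, had a value of -0.10 (SE 0.16), and Cartpt, encoding CART, of -0.03 (SE 0.08). The growth hormone regulators Ghrh (-0.02, SE 0.11) and Sst (-0.03, SE 0.06), the leptin receptor gene Lepr (-0.05, SE 0.18), the insulin receptor gene Insr (0.01, SE 0.03) and the dopamine genes Th (0.10, SE 0.17) and Drd2 (0.07, SE 0.09) also missed the threshold. The same was true of Hcrt (0.12, SE 0.12), Pmch (-0.08, SE 0.12), Mc4r (0.10, SE 0.12), Brs3 (0.04, SE 0.12), Avp (-0.03, SE 0.11), Oxt (0.01, SE 0.20), Crh (0.21, SE 0.18), Trh (-0.001, SE 0.08), Gfap (0.001, SE 0.10) and Socs3 (0.02, SE 0.12).

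Immediate early genes, which neurons induce within minutes of stimulation, had the lowest values on control diet in the knockout. The mean of the 18 genes was 8.57 ± 0.49 in KO_CD and 9.16 ± 0.39 in WT_CD on the log2 scale (SD), a difference of -0.59 (exact permutation p = 0.0274). None of the 18 passed over all genes, and 11 were lower when adjusted over the list alone, including Dusp1, a phosphatase that silences MAP kinases (-0.70, SE 0.21), and Fosb, a subunit of AP-1 (-1.05, SE 0.32). The list was lower by camera with the preset correlation (adjusted p = 1.37e-20), with adjusted p = 0.143 with an estimated correlation. By permutation the adjusted p over the 37 lists was 0.337. Within mice of 149 days the difference was -0.86 (exact permutation p = 0.00649, 5 against 6 mice). Control-diet mice of 150 days were 3 knockouts and 1 wild type, too few for a value of their own.

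**Figure D2:**
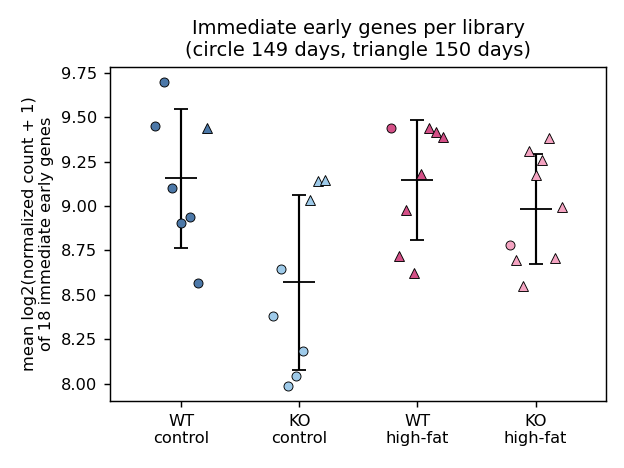
Mean log2(normalized count + 1) of 18 immediate early genes per library, with group mean ± SD as bars, circles for mice of 149 days and triangles for mice of 150 days. KO_CD averaged 8.57 and WT_CD 9.16, and among KO_CD mice those of 150 days lay 0.86 above those of 149 days.

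Several cell type lists differed between genotypes on control diet by camera with the preset correlation, with no member called over all genes or when adjusted over the list alone. Oligodendrocyte genes (15 tested, median 0.09, adjusted p = 3.52e-08) were higher in all 15 members, among them Hapln2 (0.17, SE 0.06) and Ermn (0.11, SE 0.05), both of myelin. Thalamic genes (16 tested, median 0.13, adjusted p = 0.00155) included Calb2 (0.12, SE 0.06), encoding calretinin. Ependymal genes (12 tested, median -0.12, adjusted p = 8.26e-05) included Rsph1 (-0.20, SE 0.08), a component of cilia, and tanycyte genes (13 tested, median -0.07, adjusted p = 0.0197) included Nes (-0.22, SE 0.08), encoding nestin. With an estimated correlation the adjusted p = 0.39 for oligodendrocytes, adjusted p = 0.595 for thalamus, adjusted p = 0.39 for ependyma and adjusted p = 0.595 for tanycytes. The sixth list, paraventricular and supraoptic neurons, held Gpr101 itself, and its median of 0.00 and mean of -0.93 parted for that reason. Without Gpr101 its median was 0.006 and the exact permutation p of its mean was 0.732.

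Across the 19928 genes, limma called 1 gene between genotypes on control diet and gave 821 genes an unadjusted p below 0.05, where 996.4 would be due to chance. Limma-voom called 1 gene with and without quality weights, and within mice of 149 days 1 gene was called. Without a filter on low counts 2 genes were called.

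On high-fat diet, genotype was compared to ask whether Gpr101 matters under a dietary load. Gpr101 was again the 1 gene called, and the smallest adjusted p among the others was 0.842. Pomc had a log2 fold change of -0.37 (SE 0.15, adjusted p = 0.948), with 1935 ± 365 normalized counts in KO_HFD and 2531 ± 589 in WT_HFD (SD). Npy (-0.14, SE 0.13), Agrp (-0.07, SE 0.14), Cartpt (-0.02, SE 0.07), Avp, encoding vasopressin (-0.20, SE 0.11), Oxt, encoding oxytocin (-0.13, SE 0.18), and Gfap, the astrocyte filament gene (-0.15, SE 0.10), missed the threshold as well. So did Ghrh (-0.12, SE 0.11), Sst (-0.09, SE 0.06), Lepr (-0.16, SE 0.17), Insr (0.03, SE 0.03), Mc4r (0.10, SE 0.11), Brs3 (0.13, SE 0.11), Th (-0.05, SE 0.16), Drd2 (-0.05, SE 0.09), Hcrt (-0.01, SE 0.11), Pmch (0.05, SE 0.12), Crh (0.10, SE 0.17), Trh (-0.06, SE 0.08) and Socs3 (0.02, SE 0.11).

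The lists that differed on high-fat diet by camera with the preset correlation moved by small amounts. Microglial genes had a median of -0.06 (adjusted p = 0.000428), and 2 of 14 were lower when adjusted over the list alone, the complement gene C1qc (-0.13, SE 0.04) and the growth factor receptor gene Csf1r (-0.08, SE 0.03). The median was -0.03 for astrocyte genes (14 tested, adjusted p = 0.000554), including Ntsr2 (-0.08, SE 0.03) and Agt, encoding angiotensinogen (-0.08, SE 0.03). It was -0.11 for ependymal genes (12 tested, adjusted p = 0.000613), including Rsph1 (-0.20, SE 0.07), and -0.14 for immediate early genes (18 tested, adjusted p = 0.00504). The mean of the immediate early genes differed by -0.164 (exact permutation p = 0.304). Transcripts of the mitochondrial genome had a median of -0.06 (13 tested, adjusted p = 6.51e-05), including mt-Nd4 (-0.06, SE 0.02) and mt-Cytb (-0.09, SE 0.03), both of which were lowest in KO_HFD replicate 8. Genes of fatty acid use had a median of -0.04 (22 tested, adjusted p = 0.0158), including Pdk4 (-0.15, SE 0.07). Genes of Gs and cAMP signalling, the pathway downstream of the receptor, had a median of 0.03 (26 tested, adjusted p = 0.0158), including Creb1 (0.11, SE 0.04). Apart from the microglial pair, no member of these lists was called over all genes or when adjusted over the list alone. In the order microglia, astrocytes, ependyma, immediate early genes, mitochondrial genome, fatty acid use and cAMP signalling, the values were adjusted p = 0.377, 0.204, 0.423, 0.627, 0.36, 0.423 and 0.377 with an estimated correlation. The eighth list was again that of paraventricular and supraoptic neurons, with a median of -0.05 and a mean of -0.97 that held Gpr101, and without Gpr101 the exact permutation p of its mean was 0.694.

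Limma gave 1026 genes an unadjusted p below 0.05 between genotypes on high-fat diet, against 996.4 by chance, and limma-voom called 1 gene with and without quality weights. Within mice of 150 days 1 gene was called. Over 19927 genes without Gpr101, the fold changes of genotype on control and on high-fat diet correlated with Pearson r = 0.034 and Spearman rho = 0.069 across genes, which are not independent replicates. Of 100 splits of the mice, the real one included here and below, 31 gave a Pearson r as high, and the highest other split gave 0.265.

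Averaged over diets, genotype left Gpr101 as the 1 called gene (log2 fold change -11.42, SE 0.08, adjusted p = 2.07e-56), and the smallest adjusted p among the others was 0.473. Within 2 Mb of Gpr101, 14 genes were tested. Arhgef6, encoding a Rac exchange factor on the X chromosome from 57231485 to 57338729, had a log2 fold change of 0.09 (SE 0.03, adjusted p over the window 0.0258 and over all genes 0.758), and Rbmx, encoding an RNA-binding protein, had 0.05 (SE 0.02, adjusted p over the window 0.0734). The list of X-linked neighbours without Gpr101 (10 genes) had a median of 0.04 (camera p = 0.000247, and p = 0.000667 with an estimated correlation), and the permutation p of its mean was 0.134. With Gpr101, 3 neighbours were higher and Gpr101 lower when adjusted over the list alone, and the median of 0.04 and the mean of -1.01 differed in sign.

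Of the lists averaged over diets, 10 differed between genotypes by camera with the preset correlation. Immediate early genes had a median of -0.41 (18 tested, adjusted p = 9.4e-17, and adjusted p = 0.128 with an estimated correlation), with 0 called over all genes, 10 lower when adjusted over the list alone and an adjusted permutation p of 0.132. Ependymal genes had a median of -0.11 (12 tested, adjusted p = 4.01e-07, and adjusted p = 0.177 with an estimated correlation), with Rsph1 (-0.20, SE 0.05) lower when adjusted over the list alone. Oligodendrocyte genes had a median of 0.05 (15 tested, adjusted p = 1.09e-05, and adjusted p = 0.514 with an estimated correlation), with Ermn (0.12, SE 0.04) higher when adjusted over the list alone. Astrocyte (median -0.03, adjusted p = 0.000383), tanycyte (-0.10, adjusted p = 0.00302), suprachiasmatic (-0.07, adjusted p = 0.0213), fatty acid use (-0.04, adjusted p = 0.00333), thalamic (0.05, adjusted p = 0.00352) and cAMP signalling genes (0.02, adjusted p = 0.00333) held no gene called over all genes or when adjusted over the list alone. In that order these lists had adjusted p = 0.128, 0.5, 0.574, 0.293, 0.574 and 0.182 with an estimated correlation. The list of paraventricular and supraoptic neurons had a median of -0.03 and a mean of -0.95 that held Gpr101, and without Gpr101 the permutation p of its mean was 0.957. Limma gave 1140 genes an unadjusted p below 0.05 between genotypes averaged over diets, and limma-voom called 1 gene with and without quality weights.

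In wild type, 5 genes were called between diets, all of them higher on high-fat diet. Age followed diet in these mice, so the comparison alone does not separate diet from age, and fits with age are given below. Serpina3n, a protease inhibitor induced in reactive astrocytes, rose 1.44-fold (log2 fold change 0.53, SE 0.09, adjusted p = 0.0137), from 1344 ± 225 to 1921 ± 217 normalized counts (SD). Slc16a1, encoding the monocarboxylate transporter MCT1, rose 1.21-fold (0.27, SE 0.05, adjusted p = 0.0137), and Stat3, the transcription factor downstream of the leptin receptor, rose 1.16-fold (0.21, SE 0.04, adjusted p = 0.0209). Stat3 was the 1 called of 21 leptin and insulin signalling genes, 2 were higher when adjusted over the list alone, and the list had a median of -0.001 and a mean of 0.05 that differed in sign (camera adjusted p = 0.514). The homeobox gene Phox2a, chosen after its values were seen because its mean lay below 1 CPM, rose by 2.17 (SE 0.36, adjusted p = 0.00459) and is described separately.

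By camera with the preset correlation, gene groups that differed between diets in wild type included feeding peptides and lipid genes. It called 10 lists, where random splits of the mice called a median of 7. By permutation of the list mean none passed (adjusted p = 0.132 for orexigenic peptides and 0.5 for cholesterol synthesis, gliosis and microglia). Orexigenic peptide genes had a median of -0.10 (adjusted p = 0.006 by camera), with 3 of 8 lower when adjusted over the list alone, among them Npy (-0.45, SE 0.14) and Agrp (-0.41, SE 0.15). Cholesterol synthesis genes had a median of -0.06 (adjusted p = 5.01e-07), with 2 of 23 lower when adjusted over the list alone, among them the enzyme gene Sqle (-0.12, SE 0.03). Gliosis and inflammation genes had a median of 0.15 (adjusted p = 1.23e-05), with Serpina3n called over all genes and 3 of 17 higher when adjusted over the list alone. Microglial genes had a median of 0.05 (adjusted p = 0.00144), with the protease gene Ctss (0.18, SE 0.04) the 1 of 14 that was higher when adjusted over the list alone. In the order orexigenic peptides, cholesterol synthesis, gliosis and microglia, the values were adjusted p = 0.138, 0.341, 0.324 and 0.401 with an estimated correlation. Smaller shifts were called for endothelium (13 tested, median 0.07, adjusted p = 0.00809, and adjusted p = 0.486 with an estimated correlation) and ventromedial neurons (13 tested, median -0.06, adjusted p = 0.032, and adjusted p = 0.552 with an estimated correlation). The same held for sex steroid and kisspeptin genes (12 tested, median -0.04, adjusted p = 0.0394, and adjusted p = 0.401 with an estimated correlation) and for glucocorticoid response genes (17 tested, median 0.06, adjusted p = 0.0455, and adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone, 1 endothelial gene was higher, Slco1a4 (0.13, SE 0.04), and 1 ventromedial gene was lower, Nos1 (-0.12, SE 0.04). Among the others 1 steroid-related gene was lower, the progesterone receptor gene Pgr (-0.14, SE 0.04), and 0 glucocorticoid genes differed, where limma gave Hif3a an unadjusted p of 0.00851.

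Markers of other tissues also differed between diets in wild type by camera with the preset correlation. By permutation of the list mean they missed the threshold (adjusted p = 0.56 for meninges and 0.21 for blood). The meningeal list mean was 7.89 ± 0.59 in WT_CD and 8.65 ± 1.11 in WT_HFD (SD), with a median fold change of 0.83 over 14 genes, all 14 of them above 0 and none called over all genes or over the list alone (adjusted p = 2.52e-07 by camera, and adjusted p = 0.41 with an estimated correlation). The blood list mean was 10.63 ± 0.14 and 10.996 ± 0.32, and 4 of 8 genes were higher when adjusted over the list alone (median 0.51, adjusted p = 8.28e-05, and adjusted p = 0.324 with an estimated correlation).

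Limma gave 1473 genes an unadjusted p below 0.05 for diet in wild type, and limma-voom called 6 genes, or 8 with quality weights. The count was 3 without WT_CD replicate 1 and 1 without WT_CD replicate 2, which left Phox2a. Stat3 passed in 9 of 15 fits that left out 1 library, with a highest adjusted p of 0.113. The count was 1 with age as a factor, 0 with the blood mean as a covariate and 1 without the 8 libraries highest in meningeal markers. With age as a factor the limma adjusted p was 0.0947 for Phox2a, 0.229 for Slc16a1, 0.273 for Serpina3n and 0.333 for Stat3, so these genes missed the threshold. Wild-type mice of 150 days on control diet numbered 1 and those of 149 days on high-fat diet numbered 1, too few for a value within an age.

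In knockouts, 7 genes were called between diets, 3 higher and 4 lower on high-fat diet, and age followed diet here as well. Serpina3n rose 1.46-fold (log2 fold change 0.55, SE 0.08, adjusted p = 0.00338), from 1344 ± 111 to 1966 ± 210 normalized counts (SD), and Slc16a1 rose 1.27-fold (0.34, SE 0.05, adjusted p = 0.000116), from 1277 ± 102 to 1615 ± 117. Phox2a rose by 2.02 (SE 0.33, adjusted p = 0.00259). Npas2, a clock transcription factor, was lower (-0.30, SE 0.06, adjusted p = 0.0347), as were Prex1, encoding a Rac exchange factor (-0.16, SE 0.03, adjusted p = 0.0264), Acsbg1, an acyl-CoA synthetase of the brain (-0.13, SE 0.03, adjusted p = 0.0347), and Scd1, the stearoyl-CoA desaturase (-0.11, SE 0.02, adjusted p = 0.0347). Phox2a, Serpina3n and Slc16a1 were called in both genotypes. The 4 lower genes had the same sign in wild type, at -0.125 for Npas2, -0.081 for Prex1, -0.048 for Acsbg1 and -0.112 for Scd1. No gene was called for the interaction, so a call in knockouts alone does not show a response particular to them.

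Among the groups in knockouts, immediate early genes had a median of 0.41 between diets (18 tested, 17 above 0, adjusted p = 2.06e-09 by camera, and adjusted p = 0.343 with an estimated correlation), with no gene called over all genes or when adjusted over the list alone, including Fos (0.84, SE 0.29). Their direction turned within knockouts of 150 days, where the list mean differed by -0.098 (exact permutation p = 0.63, 8 against 3 mice) and Fos by -0.135, against a list mean of 0.41 over all knockouts. Leptin and insulin signalling genes had a median of 0.03 (21 tested, adjusted p = 0.00645, and adjusted p = 0.343 with an estimated correlation), with 2 higher when adjusted over the list alone, Stat3 (0.18, SE 0.04) and Socs3, its feedback inhibitor (0.53, SE 0.11). Gliosis genes had a median of 0.10 (17 tested, 1 called, 2 higher when adjusted over the list alone, adjusted p = 0.00597, and adjusted p = 0.481 with an estimated correlation), while their member C3, of complement, had -0.30 (SE 0.12). Astrocyte genes had a median of -0.04 (14 tested, adjusted p = 0.00645, and adjusted p = 0.343 with an estimated correlation), with Agt (-0.11, SE 0.03) the 1 lower when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.04 (23 tested, adjusted p = 0.00486, and adjusted p = 0.632 with an estimated correlation), with 3 lower when adjusted over the list alone, among them Mvd (-0.20, SE 0.06), an enzyme of the mevalonate pathway. Transcripts of the mitochondrial genome had a median of -0.05 (13 tested, none called over all genes or over the list alone, adjusted p = 9.42e-06, and adjusted p = 0.343 with an estimated correlation), and mt-Co2 (-0.11, SE 0.04) was lowest in KO_HFD replicate 8.

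The meningeal list mean was 8.06 ± 0.73 in KO_CD and 8.40 ± 0.86 in KO_HFD (SD), with a median fold change of 0.29 over 14 genes and none called over all genes or over the list alone (adjusted p = 0.0455, and adjusted p = 0.82 with an estimated correlation). The blood list mean was 10.66 ± 0.20 and 10.97 ± 0.24, and 4 of 8 genes were higher when adjusted over the list alone (median 0.38, adjusted p = 0.000149, and adjusted p = 0.343 with an estimated correlation).

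Limma gave 1402 genes an unadjusted p below 0.05 for diet in knockouts, and limma-voom called 7 genes, or 8 with quality weights. The count was 4 without KO_CD replicate 3, 3 without KO_CD replicate 6, 4 without KO_HFD replicate 7 and 3 without KO_HFD replicate 8. The 4 lower genes passed in 6 to 13 of the 17 fits that left out 1 library, while Serpina3n, Slc16a1 and Phox2a passed in all 17. With total counts as library sizes 4 genes were called, 3 higher and 1 lower, with the meningeal mean as a covariate 12 and with the blood mean 3, and within mice of 150 days 2 genes were called. Over 19927 genes without Gpr101, the fold changes of diet in wild type and in knockouts, which share no library, correlated with Pearson r = 0.234 and Spearman rho = 0.208 across genes, which are not independent replicates. Of the 1473 genes with an unadjusted p below 0.05 in wild type, 75.1% had the same sign in knockouts. Of 100 splits of the mice, 3 gave a Pearson r as high, and the highest other split gave 0.357.

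Averaged over genotypes, 37 genes were higher and 30 lower on high-fat diet, and the median absolute log2 fold change of the 67 was 0.15. Slc16a1 rose 1.24-fold (0.31, SE 0.03, adjusted p = 4.86e-07) and was higher than the control-diet mean of its genotype in 17 of 17 high-fat libraries. Serpina3n rose 1.45-fold (0.54, SE 0.06, adjusted p = 1.21e-05), Socs3 1.44-fold (0.53, SE 0.08, adjusted p = 0.000295) and Stat3 1.14-fold (0.19, SE 0.03, adjusted p = 5.34e-05), each in 17 of 17. Gpr151, an orphan receptor gene of the habenula, rose 1.60-fold (0.68, SE 0.12, adjusted p = 0.00139), from 29.5 ± 6.57 to 45.6 ± 11.04 normalized counts in wild type (SD). The values of the 67 genes had the same sign in both genotypes, and their smallest unadjusted p for an interaction was 0.0397. These genes were chosen by their mean over both genotypes in the same libraries, which favours equal signs and small interactions. The counts of high-fat libraries above or below the control mean, here and below, carry the same limit and are not separate support.

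Feeding peptide genes moved in both directions with diet. Hcrt, encoding the arousal and feeding peptide orexin, was lower (-0.37, SE 0.08, adjusted p = 0.0362), Cartpt was higher (0.32, SE 0.05, adjusted p = 0.00139) and Avp was higher (0.34, SE 0.08, adjusted p = 0.0477). With age as a factor Hcrt, Cartpt and Avp missed the threshold (limma adjusted p = 0.206, 0.125 and 0.242). Npy (-0.32, SE 0.10, adjusted p = 0.162), Agrp (-0.31, SE 0.11, adjusted p = 0.239), Ghrh (-0.23, SE 0.08, adjusted p = 0.216) and Pomc (0.11, SE 0.11, adjusted p = 0.778) missed the threshold. Sst (-0.06, SE 0.04), Mc4r (-0.06, SE 0.08), Brs3 (0.05, SE 0.08), Th (0.02, SE 0.12), Drd2 (0.003, SE 0.06), Pmch (0.01, SE 0.09), Oxt (-0.03, SE 0.13), Crh (0.11, SE 0.12) and Trh (-0.04, SE 0.06) had adjusted p-values of 0.651 or above. Orexigenic peptide genes held 1 called gene, Hcrt, and 3 of 8 were lower when adjusted over the list alone (median -0.05, adjusted p = 0.0122 by camera, and adjusted p = 0.187 with an estimated correlation). By permutation of the list mean the difference was -0.13 (adjusted p = 0.0129). Of 12 anorexigenic peptide genes, Cartpt was the 1 called, over all genes and when adjusted over the list alone, and camera gave the list an adjusted p of 0.266, with a median of -0.007 and a mean of 0.04 that differed in sign.

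Leptin and insulin signalling genes held 2 called genes of 21, Stat3 and Socs3, the same 2 when adjusted over the list alone. The list missed the threshold by camera (median 0.01, adjusted p = 0.0521), and the permutation of its mean gave 0.06 (adjusted p = 0.0222). Lepr (0.18, SE 0.13) and Insr (0.01, SE 0.02) were not called. Gliosis and inflammation genes had a median of 0.17 (17 tested, adjusted p = 7.01e-06, and adjusted p = 0.253 with an estimated correlation), with 2 called over all genes and over the list alone, Serpina3n and the complement gene C4b (0.37, SE 0.07, adjusted p = 0.00539). By permutation of the list mean the gliosis list missed the threshold (adjusted p = 0.176). Gfap had 0.03 (SE 0.07, adjusted p = 0.91). Of 14 microglial genes, Ctss was the 1 called (0.14, SE 0.03, adjusted p = 0.00998), over all genes and over the list alone, and camera gave the list an adjusted p of 0.132. Nlrc5, a regulator of antigen presentation genes, rose 1.32-fold (0.40, SE 0.08, adjusted p = 0.00733).

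Some metabolic and clock genes were called. Of 22 genes of fatty acid use, 2 rose, among them Acaa2, a thiolase of mitochondrial beta oxidation (0.19, SE 0.03, adjusted p = 0.00269). Fabp7, a fatty acid binding protein of glia (-0.24, SE 0.05, adjusted p = 0.0202), fell. When adjusted over the list alone 4 were higher and 1 lower, and camera gave the list an adjusted p of 0.0524. Gpd1, a glycerol phosphate dehydrogenase (-0.24, SE 0.05, adjusted p = 0.00633), Acot11, an acyl-CoA thioesterase (-0.15, SE 0.03, adjusted p = 0.00471), and Apln, encoding apelin (-0.21, SE 0.03, adjusted p = 0.000314), were lower. Cholesterol synthesis genes had a median of -0.05 with none of 23 called and 7 lower when adjusted over the list alone, among them Dhcr7 (-0.08, SE 0.02) and the regulator Srebf2 (-0.07, SE 0.02). Camera gave adjusted p = 6.18e-07 (adjusted p = 0.317 with an estimated correlation), and the permutation of the list mean missed the threshold (adjusted p = 0.0944). Of 18 clock genes, Npas2 (-0.21, SE 0.04, adjusted p = 0.0118) and Arntl, encoding BMAL1 (-0.15, SE 0.03, adjusted p = 0.015), were lower and Bhlhe41, a clock repressor (0.10, SE 0.02, adjusted p = 0.0305), was higher. When adjusted over the list alone 3 were higher and 3 lower, and camera gave the list an adjusted p of 0.827, with a median of 0.009 and a mean of -0.004 that differed in sign.

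The glial and homeobox genes Nkx6-2 (-0.13, SE 0.03, adjusted p = 0.0434), Fam107a (-0.13, SE 0.03, adjusted p = 0.0404) and Htra1, a serine protease (-0.12, SE 0.03, adjusted p = 0.0117), were lower on high-fat diet. Astrocyte genes had a median of -0.02 with none of 14 called and 3 lower when adjusted over the list alone, among them Aldh1l1 (-0.07, SE 0.02) (adjusted p = 0.0253, and adjusted p = 0.479 with an estimated correlation). Immediate early genes (18 tested, median 0.22, adjusted p = 0.000195, and adjusted p = 0.479 with an estimated correlation) and glucocorticoid response genes (17 tested, median 0.05, adjusted p = 0.0224, and adjusted p = 0.479 with an estimated correlation), the latter including Tsc22d3 (0.14, SE 0.06), held no gene called over all genes or over the list alone. By permutation of the list mean the adjusted p was 0.377 for astrocyte genes and 0.369 for both immediate early and glucocorticoid response genes. With age as a factor the mean of the immediate early genes went from 0.20 (SE 0.14) to -0.048 (SE 0.165).

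Erythrocyte transcripts were higher on high-fat diet. The near-identical copies Hba-a1 and Hba-a2, encoding alpha globin, rose by 0.59 (SE 0.13, adjusted p = 0.0468 and 0.0412), and Hbb-bs and Hbb-bt, encoding beta globin, by 0.62 and 0.61 (SE 0.14, adjusted p = 0.0381 and 0.0473), and of the KO_HFD libraries replicate 4 was highest in each. Reads of such copies can be split between them by the counting, which was not given. Age followed diet, and with age as a factor no globin gene was called (limma adjusted p of 0.514 or above). In KO_CD the blood list mean was 10.764 to 10.997 at 150 days and 10.375 to 10.616 at 149 days. The rise in erythrocyte transcripts was therefore not separated from age. Of the 8 blood genes 4 were called and 5 were higher when adjusted over the list alone (median 0.45, adjusted p = 2.22e-06 by camera, and adjusted p = 0.187 with an estimated correlation), and the permutation of the list mean gave 0.34 (adjusted p = 0.00407). Meningeal genes had a median of 0.55 with all 14 above 0 and none called over all genes or over the list alone, including Col3a1 (0.65, SE 0.31) (adjusted p = 2.22e-06, and adjusted p = 0.479 with an estimated correlation). By permutation of its mean the meningeal list missed the threshold (adjusted p = 0.316).

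**Figure D3:**
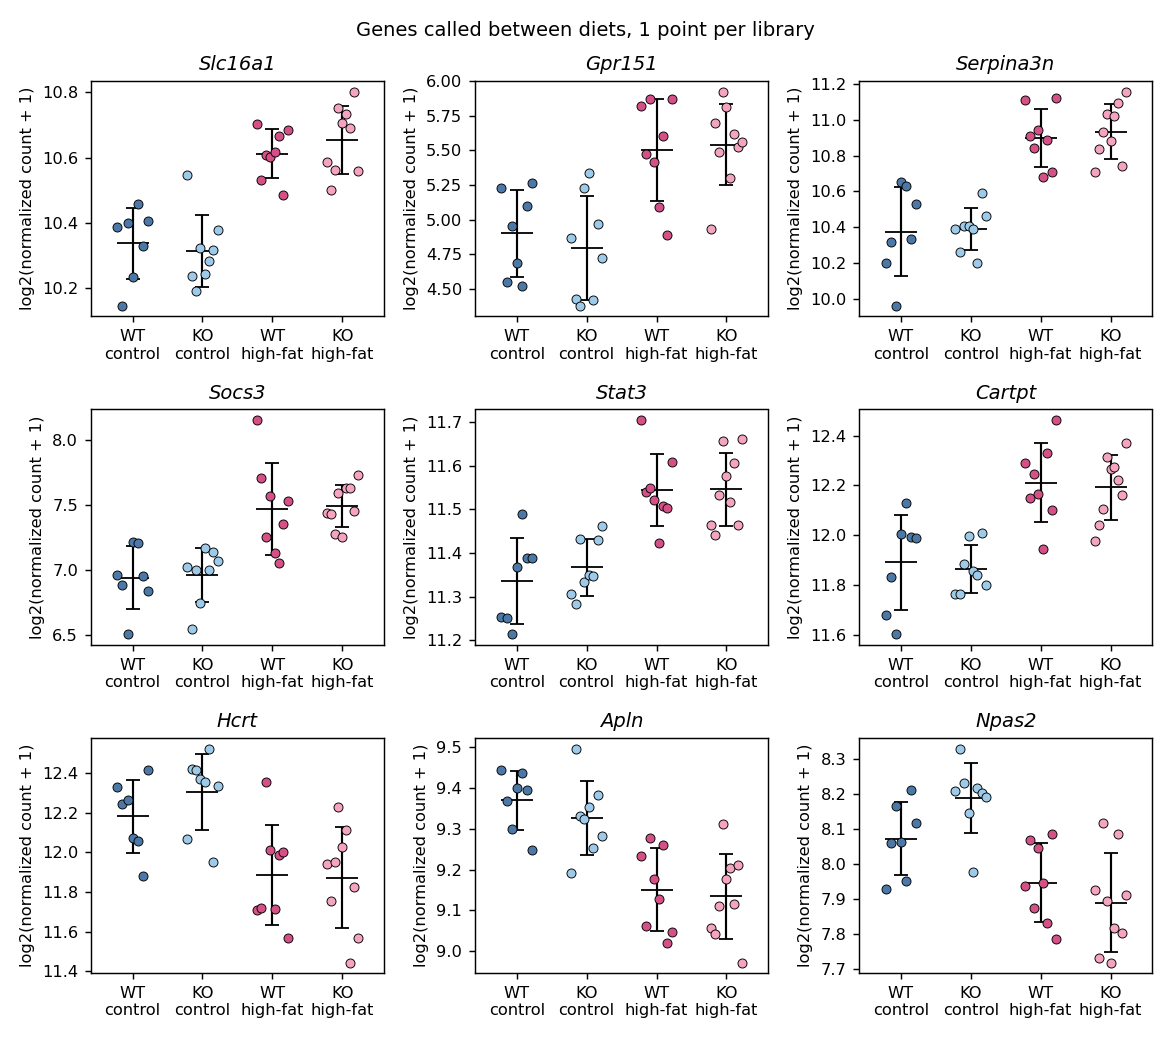
Normalized expression, as log2(normalized count + 1), of 9 genes called between diets, with 1 point per library and group mean ± SD as bars. The axes do not start at 0. Slc16a1 averaged 1296 normalized counts in WT_CD, 1277 in KO_CD, 1566 in WT_HFD and 1615 in KO_HFD.

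Limma gave 2208 genes an unadjusted p below 0.05 for diet averaged over genotypes, and limma-voom called 60 genes, or 75 with quality weights. With total counts as library sizes 71 genes were called, 48 higher and 23 lower. Age followed diet, and with age as a factor 12 genes were called, 9 of them among the 67, which included Serpina3n, Socs3, Stat3, Slc16a1 and Phox2a. With the blood mean as a covariate 18 genes were called, 15 of them among the 67, and with the meningeal mean 42, of which 34. Without the 8 libraries highest in meningeal markers 18 were called, of which 15. The count was 43 without KO_CD replicate 5, 44 without WT_CD replicate 1, 41 without WT_CD replicate 2 and 41 without WT_CD replicate 6. Over the 32 fits that left out 1 library, followed for 28 called genes, Hbb-bs passed in 17, Hcrt in 16, Hba-a2 in 14, Nkx6-2 in 13, Fam107a in 12, Hba-a1 and Hbb-bt in 10, Avp in 6 and Bhlhe41 in 23, and the other 19 passed in all 32.

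Phox2a (ENSMUSG00000007946, GRCm38 chromosome 7, 101818313 to 101822726, plus strand), a transcription factor of noradrenergic neurons, had the largest fold change of the called genes averaged over genotypes (2.09, SE 0.24, adjusted p = 4.86e-07), and it was chosen after its values were seen. It rested on few reads, at 0.372 CPM over all libraries. The 15 control-diet libraries held 0 to 7 reads each and the 17 high-fat libraries 10 to 27, at 3.67 ± 2.29 and 16.4 ± 4.44 normalized counts (SD). The lowest high-fat value of 10.2 lay above the highest control value of 7.30. Its last bases overlap those of Inppl1 on the opposite strand, which runs from 101822632 to 101838229.

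**Figure D4:**
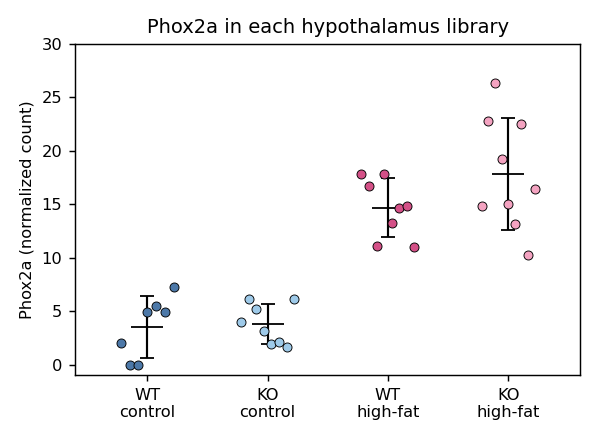
Phox2a in normalized counts, on a linear axis, with 1 point per library and group mean ± SD as bars. The 17 high-fat libraries lay at or above 10.2 and the 15 control libraries at or below 7.30.

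The interaction asked whether the response to diet differed between genotypes. No gene was called by limma (0 of 19928, with 676 at an unadjusted p below 0.05 against 996.4 by chance), and limma-voom called 0 with and without quality weights. Npy (0.25, SE 0.20), Agrp (0.22, SE 0.21), Pomc (-0.27, SE 0.22), Cartpt (0.01, SE 0.10), Socs3 (0.00, SE 0.16) and Hcrt (-0.13, SE 0.16) missed the threshold, each with an adjusted p of 0.999 or above. By camera with the preset correlation 5 lists differed, with no member called over all genes or over the list alone. Immediate early genes had a median of 0.46 (adjusted p = 1.12e-05), including Fosb (0.93, SE 0.44), and microglial genes of -0.07 (adjusted p = 0.000723), including Trem2 (-0.29, SE 0.11). The median was -0.07 for oligodendrocyte genes (adjusted p = 0.00309), -0.38 for meningeal genes (adjusted p = 0.0177) and -0.08 for transcripts of the mitochondrial genome (adjusted p = 2.55e-05). The same lists in that order had adjusted p = 0.838, 0.807, 0.838, 0.838 and 0.807 with an estimated correlation.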

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

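The tests of age, label numbers and place within a run were chosen only after the immediate early genes had been seen, and the splits of the mice were planned. Values of single libraries are on the log2(normalized count + 1) scale. Over 98 quantities and 392 tests of a group, 36 values of single libraries stood apart from the others of their group by the gap to the nearest value relative to the range, where chance gives about 1 in 20 groups.

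Several of these values came from the same library. In KO_HFD replicate 4 the globin genes were high, with Hba-a1 at 13.57 (others 12.25 to 12.88), Hba-a2 at 12.55 (11.23 to 11.88), Hbb-bs at 13.7 (12.49 to 13.01) and Hbb-bt at 11.91 (10.62 to 11.21), Acaa2 was low at 8.88 (9 to 9.11), and Gpr101 was at 1.01 from 1 read (0 in the others). In KO_HFD replicate 8 the mitochondrial transcripts were low, with mt-Co2 at 16.52 (16.75 to 16.99), mt-Cytb at 16.49 (16.76 to 16.88) and mt-Nd4 at 16.52 (16.65 to 16.73), the mitochondrial share was 4.18% (4.44 to 4.66%), and Ntsr2 was low at 11.96 (12.04 to 12.12). In KO_CD replicate 1, C3 at 7.73 (6.73 to 7.17), Col3a1 at 8.47 (6.29 to 7.21) and Lepr at 8.25 (7.37 to 7.65) were high. In KO_CD replicate 3, Fam107a at 12.54 (12.16 to 12.33) and Hif3a at 7.64 (6.18 to 6.79) were high. In KO_CD replicate 6, Oxt at 11.82 (12.4 to 12.89) and Trh at 10.86 (11.18 to 11.35) were low. In WT_CD replicate 4, Aldh1l1 at 10.34 (10.45 to 10.53), Dhcr7 at 10.04 (10.14 to 10.22) and Scd1 at 13.16 (13.21 to 13.25) were low. In WT_HFD replicate 6, Acaca was low at 11.48 (11.67 to 11.79) and Fgf13 high at 11.26 (10.98 to 11.11), and in WT_HFD replicate 7, Acsbg1 was high at 12.17 (12.03 to 12.08) and Creb1 low at 10.46 (10.58 to 10.67).

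Other libraries stood apart in 1 quantity each. Values were low for Acot11 in KO_HFD replicate 6 at 9.9 (others 10.08 to 10.25), C1qc in WT_CD replicate 1 at 9.42 (9.5 to 9.56), Ghrh in WT_HFD replicate 5 at 6.33 (6.76 to 7.14), Hapln2 in KO_HFD replicate 7 at 9.66 (9.92 to 10.06), Mc4r in KO_CD replicate 5 at 5.65 (6.24 to 6.68), Nlrc5 in KO_HFD replicate 1 at 5.99 (6.48 to 6.92), Npy in KO_HFD replicate 3 at 7.54 (7.82 to 8.08), Oxt in WT_CD replicate 5 at 11.42 (12.39 to 13.01) and Srsf2 in WT_CD replicate 2 at 11.52 (11.63 to 11.68). Th was high in WT_HFD replicate 2 at 10.7 (9.64 to 10.11), and KO_CD replicate 7 held 34.19 M reads (26.18 to 28.62 M).

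The response to diet differed between genotypes for 5 lists by the interaction in camera with the preset correlation. The adjusted p was 1.12e-05 for immediate early genes, 0.000723 for microglia, 0.00309 for oligodendrocytes, 0.0177 for meninges and 2.55e-05 for the mitochondrial genome, and 0.838, 0.807, 0.838, 0.838 and 0.807 with an estimated correlation. Of 100 splits of the mice, 75 called as many lists for the interaction, so chance was not excluded (real value 5, highest other 15).

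Immediate early genes were lower in KO_CD than in WT_CD mice by a list mean of -0.587. The tables argue against age as the whole cause, since within mice of 149 days the difference was -0.862 (exact permutation p = 0.00649), and against the run of label numbers, since with the run as a factor it was -0.652 (permutation p within runs 0.0123). The place within a run of label numbers stays open, because 0 KO_CD mice had a place that a WT_CD mouse also had, so that place and genotype cannot be told apart, and 55 of 100 splits of the mice called as many lists as the real one (real value 6, highest other 13). Among KO_CD mice, those of 150 days lay 0.86 above those of 149 days (exact permutation p = 0.0179, 3 against 5 mice, the smallest p that 56 splits can give). These 3 mice, at 9.034, 9.141 and 9.147, lay near the WT_CD mean of 9.157, so the difference rests on the knockouts of 149 days. On high-fat diet the genotype difference of the list mean was -0.164 (exact permutation p = 0.304). A lower neuronal activity without Gpr101 may contribute, and these values and the adjusted permutation p of 0.337 over the 37 lists leave it a hypothesis.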

How the results depend on the processing

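Alternatives chosen after seeing the data were the deposited log2 values, pseudocounts of 0.5 and 5, total counts, limma-voom without quality weights, residual components, the meningeal and blood covariates, the fits without the 8 libraries highest in meningeal markers and within knockouts of 150 days, the permutation and Gpr101-free tests of lists, and the fits of the immediate early list mean by age. The planned quasi-likelihood and Wald tests of counts and surrogate variables were not run. The deposited unit is log2 and the test was chosen for it, although the recovered whole reads would have allowed tests of counts. The planned unstranded column did not apply, and TMM and median-of-ratios library sizes changed places as alternative and main choice. The count of called genes stayed within 1.5 times the main one in 18 of 19 settings for genotype on control diet, 19 of 19 on high-fat diet, 16 of 17 for genotype averaged over diets, 16 of 17 for the interaction, 11 of 18 for diet in wild type, 14 of 19 for diet in knockouts and 11 of 17 for diet averaged over genotypes. No named gene reversed its direction in a called comparison. Depth limited genes such as Phox2a, at 0.372 CPM, where 1 read was 0.0361 CPM at the median depth.

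Except where stated, the cause was not tested. The immediate early list mean turned from 0.202 to -0.048 with age as a factor for diet averaged over genotypes, and from 0.414 to -0.098 within knockouts of 150 days. Without a filter, genotype on control diet called 2 genes and diet averaged over genotypes 43, all 43 among the main calls, with 41338 genes tested in place of 19928. For diet in wild type, where the main count was 5, limma-voom with quality weights gave 8 (6 without them), only the 2 groups compared gave 2, age as a factor 1, the blood mean 0 (limma) and leaving out the 8 libraries highest in meningeal markers 1. For diet in knockouts, where it was 7, total counts gave 4, the meningeal mean 12, the blood mean 3 and knockouts of 150 days 2. For diet averaged over genotypes, where it was 67, age gave 12, the meningeal mean 42, the blood mean 18 and leaving out those 8 libraries 18. With the first 3 residual principal components, which are built from the residuals of the groups and so lower the spread by construction, the counts were 292 for diet in wild type, 72 for diet in knockouts, 6 for genotype averaged over diets, 677 for diet averaged over genotypes and 1 for the interaction.

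Leaving out each library in turn gave 1 to 1 called genes in each of the 3 genotype comparisons, 1 to 7 for diet in wild type, 3 to 10 for diet in knockouts, 41 to 87 for diet averaged over genotypes and 0 to 0 for the interaction. The lowest counts came without WT_CD replicate 2 (1 and 41), WT_CD replicate 6 (41) and KO_CD replicate 6 and KO_HFD replicate 8 (3 each).

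The replicate numbers did not pair the mice across all groups. Same-numbered libraries correlated between -0.195 and 0.321, and in no pair of groups did every pair exceed 0.1 or every library correlate best with its own number. Between KO_HFD and WT_HFD, 4 of 8 same-numbered pairs exceeded 0.1 and 4 libraries correlated best with their own number, with a mean of 0.095. In each other pair of groups at most 2 did either. A partial link between the numbers in the high-fat groups was therefore not excluded. With the replicate block, diet in wild type called 3 genes against 5, which was the 1 count that moved by over 1.5 times, and diet averaged over genotypes called 45, of which 42 were among the 67.

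For the 37 lists, in the order genotype on control diet, genotype on high-fat diet, diet in wild type, diet in knockouts, genotype averaged, diet averaged and interaction, camera with the preset correlation called 6, 8, 10, 8, 10, 8 and 5. With an estimated correlation it called 0, 0, 0, 0, 0, 0 and 0. Directional fry called 2, 2, 0, 0, 2, 3 and 0, and mixed fry 2, 2, 1, 1, 2, 5 and 0. The permutation of the list mean per library called 2, 2, 0, 0, 2 and 3, without the interaction, and the 2 lists in each genotype comparison were those that hold Gpr101. Camera without Gpr101 in the lists called 5, 8 and 10 for the 3 genotype comparisons.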

Other observations

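The tests of explanations here were chosen only after the results had been seen, except that the fit with age as a factor and the splits of the mice were planned. Averaged over genotypes, some genes of fatty acid synthesis were lower on high-fat diet, and they were chosen after their values were seen, with no test of the pathway. The desaturase genes Scd1 (-0.11, limma adjusted p = 5.34e-05), Scd2 (-0.06, SE 0.01, adjusted p = 0.00249) and Fads1 (-0.07, SE 0.02, adjusted p = 0.0123) lay below the control-diet mean of their genotype in 17 of 17 high-fat libraries, and Fads2 (-0.08, SE 0.02, adjusted p = 0.0101) and Acaca, encoding acetyl-CoA carboxylase (-0.09, SE 0.02, adjusted p = 0.0474), in 16 of 17. Their signs held with TMM and total counts as library sizes, and with total counts Acaca missed the threshold (adjusted p = 0.066).

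Single genes that were higher on high-fat diet, also chosen after their values were seen, were not tested as groups. Irf9, a subunit of the interferon-stimulated transcription factor (0.25, SE 0.04, limma adjusted p = 0.00133), and Slc38a2, encoding a glutamine transporter (0.26, SE 0.06, adjusted p = 0.0305), lay above the control mean in 17 of 17 high-fat libraries. The splicing genes Hnrnph1 (0.08, adjusted p = 0.0361) and Srsf2 (0.07, SE 0.02, adjusted p = 0.0474) did so in 16 and 15 of 17, with the same signs under TMM and total counts, and with TMM Srsf2 missed the threshold (adjusted p = 0.0504).

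Age, blood and meninges were weighed for the 63 diet-averaged calls other than the globin genes. The median ratio of adjusted to unadjusted log2 fold change was 0.998 with age as a factor (95% bootstrap interval 0.961 to 1.046), 1.031 with the blood mean (0.912 to 1.067) and 0.959 with the meningeal mean (0.915 to 0.978). The intervals resampled these genes, which share the same mice and are not independent, so they leave out the spread between mice. Fold changes that stayed this close to the unadjusted ones argue against each as the whole cause for the set of genes, within that limit. Many single calls ended with age or blood in the fit, and the reason was not tested gene by gene. The median SE rose from 0.0294 to 0.0377 with age and 0.0367 with blood, while the median absolute log2 fold change went from 0.136 to 0.129 and 0.139. With the meningeal mean these were 0.0298 and 0.134. An effect of the diet itself may underlie the pattern and stays a hypothesis, and other differences in handling between the diets were not tested.

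For Phox2a on high-fat diet, reads of the overlapping gene Inppl1, age and noradrenergic cells from another region were weighed. Inppl1 differed by 0.046 on the log2 scale (-0.017 to 0.108) against 2.093 for Phox2a, and with age as a factor Phox2a rose by 2.013. The summed normalized counts of Dbh and Slc6a2, abundant in noradrenergic cells, differed by -1.86 (95% bootstrap interval -5.72 to 0.847) while Phox2a rose by 12.67, with Dbh at 3.00 in WT_CD, 2.39 in WT_HFD, 2.78 in KO_CD and 1.47 in KO_HFD. The values for age and for such cells argue against either as the whole cause. Inppl1 averaged 739.3 normalized counts in WT_CD, 783.7 in WT_HFD, 750.9 in KO_CD and 753.6 in KO_HFD. At that level its fold change cannot show whether a few of its reads were counted for Phox2a, so Inppl1 stays open. A low level of transcription at Phox2a that follows diet may be the source, and reads along the gene were not analysed here.

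Of 100 splits of the mice, the real one included, 3 gave as many called genes as the real one for diet in wild type (real value 5, highest other 159). For diet averaged over genotypes 2 did (67, highest other 143), and for diet in knockouts only the real one did (7, highest other 2). The splits argue against chance for the count in knockouts. In wild type and averaged over genotypes such counts were rare, but some splits called more genes, so chance was not excluded. For the interaction the real count was 0, which 100 splits reach by construction (highest other 2, with 676 genes at an unadjusted limma p below 0.05 and 0 by limma-voom), so they decide nothing. In the genotype comparisons the count of 1 was the deleted gene Gpr101 itself, so the splits decide nothing there, with 2 as high on control diet (1, highest other 4), 5 on high-fat diet (1, highest other 1) and 5 averaged over diets (1, highest other 23). Splits with 159 and 143 calls point to a structure among the mice that was not identified. In these splits the blood list differed by -0.104 and -0.082 (SD within groups 0.224), the meningeal list by -0.344 and -0.199 (0.809), the choroid plexus list by -0.037 and -0.02 (0.251) and immediate early genes by 0.185 and 0.025 (0.367), all within that spread. With 3 residual components only the real split gave as many calls (677, highest other 651). For the numbers of lists chance was not excluded in any comparison, with 40 splits as high for genotype on high-fat diet (8, highest other 14), 20 for diet in wild type (10, highest other 14), 28 for diet in knockouts (8, highest other 15), 21 for genotype averaged (10, highest other 17) and 35 for diet averaged (8, highest other 17).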
